A study of Mus musculus with 5 samples.

How the data were processed

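Poly(A)-primed cDNA was made from Kit-positive AML1-ETO9a leukaemia cells with a SMART-Seq v4 low-input kit and turned into libraries with Nextera XT, per the labels' protocols. Reads were single-end, 50 bp, from an Illumina sequencer, per the series' design text. Neither kit marks the strand of the transcript. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR (no version given), DESeq2 1.12.4 and the mm10 mouse genome were used. The gene annotation and the counting settings are not given in the sources used here.

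The deposited data hold 3 kinds of values. For each of the 5 libraries the authors deposited a table of whole-number read counts for 46603 genes, plus 5 rows that name no gene. A series table gives the authors' normalized signal, which equals those counts divided by 1 size factor per library. The other series table gives values on a log2 scale, made by the authors with a transformation whose name is not given in the sources used here. Both series tables list the 27526 genes with at least 2 counts in sum. The tests used the counts; the series tables gave symbols for 27526 genes and a check of what they hold. Symbols of a further 18659 genes came from a table of gene names, and 418 identifiers had none. Coordinates are from GENCODE M21 on GRCm38, the same build as mm10, in which 46005 identifiers were found.

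Rows that name no gene stayed out of library sizes and tests. Reads without a feature were 5.89% to 8.09% of all reads in a library's table, ambiguous reads 2.36% to 2.78%, unaligned reads 2.48% to 4.13% and reads aligned to several places 13.0% to 15.1%. Multiply aligned reads left out in this way lower the counts of genes with near-identical copies. Gene counts per library ran from 37306507 to 57133771, so a count of 3 corresponds to 0.0526 to 0.0723 CPM. Such limits cover counting error only, because PCR copies were not told apart.

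Groups came from the genotype in the labels: 2 libraries labelled Plcg1 wild-type and 3 labelled Plcg1 deleted. Genes were kept with edgeR's filterByExpr, which left 16120, scaled with TMM factors, and tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest; edgeR 4.0.16, limma 3.58.1, R 4.3.3) on an intercept and the genotype, leaving 3 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 was a call. CPM values use the TMM-scaled library size. The standard error of a log2 fold change was taken as its size over the square root of F. An exact permutation test of 2 against 3 libraries cannot give a two-sided p under 0.1, so none was used for single values. Libraries were first checked for copies: counts of every pair differed by more than counting noise (chi-square per gene of 50.6 or more), so none was another library deposited again. That check says nothing on whether they came from separate mice or cell preparations.

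For the comparison, 33 gene lists were fixed before the data were examined. They cover phospholipase C genes, calcium and NFAT signalling, diacylglycerol and RAS-MAPK signalling, stem cell genes, AML1-ETO associated genes, 10 lists of cell type markers, cell cycle, growth, metabolism, stress and inflammation lists, and quality lists. Each with at least 5 tested members was tested with camera at a preset correlation of 0.01. In the main fit of all 5 libraries the adjustment covered 32 lists, and the sex-linked list had 4 tested members and was not tested. Some alternatives kept at least 5 of its members and tested it, with no call. Camera was also run with the correlation estimated per list, and fry as a rotation test. None of the 9 lists that camera called across all 5 libraries kept its call with an estimated correlation, and fry called none in a direction. Members were counted after adjustment over all genes and after adjustment over the list alone.

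The rule for named genes was also fixed before the data were examined. Plcg1 comes first. Next come the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 3, groups that do not overlap and a symbol that is not a clone name. With fewer than 10 calls the 20 genes with the smallest unadjusted p replace them. Up to 2 called members each way are then named from each list, or the 2 with the smallest p. After the data were seen, the same rule was applied to the fit without deleted 6, and every other gene named, list examples included, was chosen after its values were seen.

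The test was checked on simulated counts with the real means, library sizes and dispersions and 50 changed genes per size and draw, in 5 draws. Genes were drawn independently and libraries of a group alike. The draws thus lacked an outlying library and genes that vary together, unlike the data, so the shares may not hold there. With all 5 libraries 0% of genes changed by 1 on the log2 scale were called, 8% at 2, 63.2% at 4 and 78.0% at 6, with 2.2 unchanged genes called per draw. Without deleted 6 the shares were 46.0%, 74.4%, 94.4% and 97.2%, with 19.6 unchanged genes called per draw. Those unchanged genes made up more than a 0.05 share of the calls, so that fit did not hold its threshold in the simulation. It leaves 2 residual degrees of freedom. The common dispersion was 0.226 with all 5 libraries and 0.0456 without deleted 6. Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings and filters, robust and minimum-fold versions of the edgeR test, the sequencing lane from the file names, and each library left out in turn. Figures were drawn with matplotlib in Python.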

Results

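Per the labels, RNA was profiled from mouse leukaemia stem cells positive for the surface receptor Kit, in an AML1-ETO9a model. AML1-ETO9a is a shortened form of the fusion between RUNX1 (AML1) and RUNX1T1 (ETO) found in human acute myeloid leukaemia. The groups differed in the labelled genotype of Plcg1, which encodes phospholipase C-γ1, an enzyme that cleaves a membrane lipid into the second messengers diacylglycerol and inositol trisphosphate. There were 2 libraries labelled wild-type (replicates 1 and 3) and 3 libraries labelled deleted (replicates 2, 4 and 6). The libraries labelled wild-type held 37306507 and 51682298 gene counts, and those labelled deleted held 53384359, 52560713 and 57133771. Between 21496 and 23809 genes had at least 1 count in a library. The labels do not say whether the libraries came from separate mice, so the p-values measure only the spread between these 5 samples, which may be technical. The comparison asks, as the series title states its theme, which transcripts go with Plcg1 in the self-renewing cells of this leukaemia.

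Plcg1 transcripts were not lower in the libraries labelled deleted. The gene (ENSMUSG00000016933.16; mm10 chromosome 2, 160731300 to 160775760, plus strand) stood at 22.1 and 34.0 CPM (read counts scaled to a common library size) in the libraries labelled wild-type. It stood at 52.998, 26.9 and 37.1 CPM in deleted 2, 4 and 6. The means were 28.0 ± 8.40 CPM (SD, n = 2) and 39.0 ± 13.1 CPM (SD, n = 3), and every library had at least 917 Plcg1 counts. The log2 fold change, deleted minus wild-type, was 0.48 ± 0.37 (SE), with an adjusted p of 0.543 in edgeR's quasi-likelihood test, and lay between 0.19 and 0.82 with single libraries left out. The counts are totals per gene, so reads from exons outside the deleted part remain in them and cannot check the deletion. The kit did not mark strand, and Zhx3 overlaps Plcg1 on the opposite strand, at 160748708 to 160872998. Since Plcg1 did not separate the groups, every group name refers to the library's label, as do all directions.

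The libraries did not fall into 2 even groups, because deleted 6 stood apart from the other 4. Lyz2, the lysozyme of macrophages and neutrophils, made up 5.27% of its gene counts and reached 68117 CPM, against 7215 to 15417 CPM in the other libraries. Ctsd, a lysosomal protease, reached 44744 CPM, against 4099 to 13005 CPM elsewhere. The fixed monocyte and macrophage list was not higher as a whole: its mean log2 CPM was 6.34 in deleted 6, 7.05 and 7.36 in the wild-type libraries, and 5.96 and 6.96 in deleted 2 and 4. Its members went both ways, with Ly6c2, a surface marker of inflammatory monocytes, at 5.45 CPM in deleted 6 and 781 and 832 CPM in wild-type. Adgre1, another member, was highest in deleted 6, at 731 CPM against 195 to 628 CPM in the other libraries. The macrophage genes Csf1r and Itgam were highest there too, at 727 against 292 to 673 CPM and 1598 against 456 to 712 CPM. The primary granule enzyme Mpo was at 4.21 CPM in deleted 6, against 2706 to 5068 CPM in the other 4, and the proliferation marker Mki67 at 7.76 CPM, against 165 to 272 CPM. Kit itself, the receptor used to select the cells, was at 26.8 and 32.1 CPM in the libraries labelled wild-type. It was at 672 and 304 CPM in deleted 2 and 4 and at 3.08 CPM in deleted 6. The 10 largest genes took 20.4% of the counts of deleted 6, against 4.76% to 8.96% in the other libraries. Across genes, the Spearman correlation was 0.988 between both wild-type libraries and 0.985 between deleted 2 and 4. Deleted 6 correlated at 0.870 to 0.922 with the others. Xist, the transcript of X inactivation, had 5375 counts in deleted 6 and at most 3 in any other library, and the Y-linked Ddx3y was at 0.271 CPM in deleted 6 and 64.0 to 92.4 CPM elsewhere. In the main fit of all 5 libraries the sex-linked list had 4 tested members, too few for a test. The genes of this paragraph were chosen after their values were seen.

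**Figure D1:**
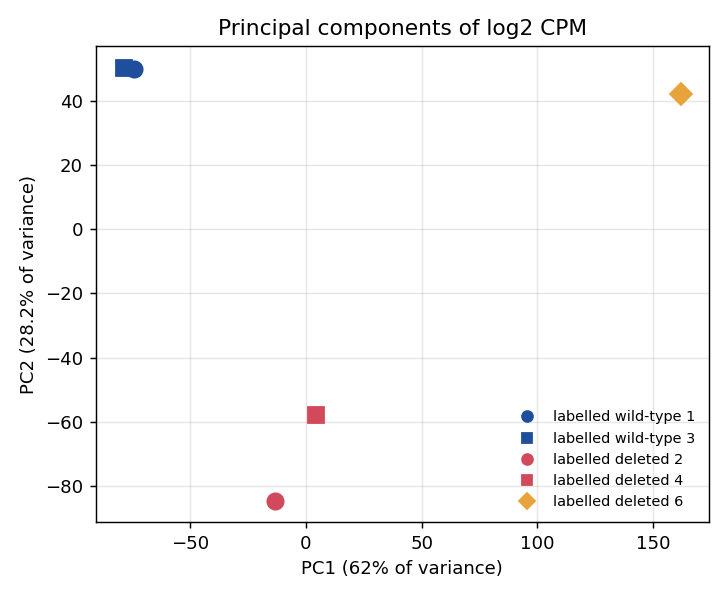
Each point is a library, placed by the first and second principal components of log2 CPM over 16120 genes; colours and shapes name the library. The first component (62.0% of the variance) sets deleted 6 apart, and the second (28.2%) places both wild-type libraries away from deleted 2 and 4.

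Across all 5 libraries, no gene passed the genome-wide test, although many genes had values that did not overlap between the labelled groups. edgeR's quasi-likelihood test called 0 of 16120 genes in either direction, with a smallest adjusted p of 0.103. At an unadjusted p under 0.05 there were 2396 genes, 1522 higher and 874 lower in the libraries labelled deleted, where 806 would fall by chance. DESeq2 called 838 genes higher and 396 lower, and limma-voom with sample quality weights called 1230 and 947. In 3604 genes (22.4%) every deleted library lay above both wild-type libraries, and in 3825 genes (23.7%) every one lay below. For a single gene chance gives 10% each way, and genes that vary together do not count as independent. Without deleted 6, a setting looked at in detail only after its values were seen, edgeR called 1245 genes higher and 800 lower among 15787. In simulated counts that fit called more unchanged genes than its threshold allows. In lane 4, the only sequencing lane in the file names with both labels, 1 wild-type and 2 deleted libraries gave 211 genes higher and 131 lower. All p-values from lane 4 alone, for genes and for lists, assume that its lone wild-type library varies like the 2 deleted ones.

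The 20 genes with the smallest unadjusted p did not pass across all 5 libraries (adjusted p from 0.103 to 0.121, edgeR), yet all 20 passed without deleted 6. Among those with higher values under the deleted label, Dusp4, a phosphatase that switches off MAP kinases, had a mean of 2.07 ± 0.0734 CPM (SD, n = 2) in wild-type and 50.5 ± 13.2 CPM (SD, n = 3) in deleted libraries. Its log2 fold change was 4.61 ± 0.33 (SE). Fgfr1, a fibroblast growth factor receptor, had a log2 fold change of 6.77 ± 0.66. Itgb3, the β3 integrin chain of platelets and macrophages, had 3.54 ± 0.29, and Maoa, which oxidises monoamines, 3.19 ± 0.23. Fkbp9, Gnb4, Btbd3, Agap1, Rbpms and Ppap2b shared this direction, at 4.23, 4.25, 6.19, 2.10, 2.47 and 3.56. On the other side, Hpgd, which breaks down prostaglandins, stood at 555 ± 71.3 CPM (SD, n = 2) in wild-type and 4.26 ± 2.12 CPM (SD, n = 3) in deleted libraries, a log2 fold change of -7.03 ± 0.54. Dlk1, a membrane protein of the Notch ligand family, had 1470 and 1715 counts in the wild-type libraries and 0, 1 and 4 counts in deleted 2, 4 and 6. H2-Q10, a class Ib histocompatibility gene, had -5.01 ± 0.31; it belongs to a family of near-identical genes, so its counts are uncertain. Cdkn2c, an inhibitor of cyclin-dependent kinases, had -2.30 ± 0.22. Fstl1, Slc4a8, Rnf43 and Kcnip3 had -2.63, -3.27, -3.66 and -6.32, and the remaining pair, Hoxa5 and Hoxa10, is described with the stem cell genes.

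Hoxa5, Hoxa7, Hoxa9 and Hoxa10, members of the stem cell list, had higher values in both wild-type libraries and were close to absent in all 3 deleted libraries. Hoxa9, a transcription factor of self-renewing progenitors (chromosome 6, 52223100 to 52231089), was at 136 ± 11.9 CPM (SD, n = 2) in wild-type and 0.857 ± 0.797 CPM (SD, n = 3) in deleted libraries. Its neighbours Hoxa10, Hoxa7 and Hoxa5 had log2 fold changes of -8.97 ± 0.91, -6.65 ± 1.05 and -5.34 ± 0.47 (SE). Meis1, a cofactor of Hox proteins, fell from 79.1 and 84.5 CPM to 8.65 and 6.80 CPM in deleted 2 and 4 (adjusted p = 0.000532 in edgeR without deleted 6), and was at 0.317 CPM in deleted 6. Other stem cell genes went the opposite way: Gata2, a regulator of stem and mast cells, was at 21.9 and 24.8 CPM in wild-type, 237 and 103 CPM in deleted 2 and 4, and 1.74 CPM in deleted 6. Of the 36 tested stem cell and self-renewal genes, edgeR called none across all 5 libraries, with 10 higher and 7 lower at an unadjusted p under 0.05, while adjusted over the list alone 7 were higher and 6 lower. DESeq2 called 9 higher and 7 lower there, and limma-voom 10 and 8. Without deleted 6, edgeR called 16 higher and 8 lower, and 18 and 9 adjusted over the list alone. As a set the list did not stand apart from other genes (camera adjusted p = 0.964, and 0.191 without deleted 6). Fry's mixed test, which counts changes either way and makes no comparison with other genes, called it across all 5 libraries (adjusted p = 0.0108). There it also called the megakaryocyte and platelet list (0.0108) and the RAS-MAPK list (0.0186). Without deleted 6 it called the stem cell list (0.00220), as it did most lists. Its median log2 fold change of 0.98 and mean of 0.46 had the opposite sign to its camera direction across all 5 libraries. The median was -0.17 without deleted 2, 0.36 without deleted 4 and 0.02 with the stricter filter. With all 5 libraries it was also 0.98 with Tek, at 0 counts in both wild-type libraries, set at its bound from 3 counts over the group. Meis1 and Gata2 were picked after their values were seen, and the Hoxa genes lie close together and were counted without strand.

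Runx1t1, the gene whose human counterpart gives the ETO part of the fusion, was nearly undetected in the libraries labelled wild-type. It had 5 and 13 counts there (0.121 and 0.234 CPM), against 6035, 3921 and 598 counts (106, 74.0 and 13.5 CPM) in deleted 2, 4 and 6. Its log2 fold change was 8.46 ± 1.28 (SE; edgeR adjusted p = 0.133), and 8.92 ± 0.35 without deleted 6 (adjusted p = 0.000225). Runx1, the source of the other part, was at 83.3 ± 4.08 CPM (SD, n = 2) in wild-type and 197 ± 33.1 CPM (SD, n = 3) in deleted libraries. That log2 fold change was 1.24 ± 0.22 (adjusted p = 0.150), and 1.32 ± 0.17 without deleted 6 (adjusted p = 0.00541). Gene counts do not tell a transcript of the fusion from one of the mouse genes. With 5 and 13 Runx1t1 counts, the fusion was barely seen in the wild-type libraries, if its reads align to the mouse gene. The list comparisons may therefore set different leukaemias against each other, and not genotypes alone. Of the 29 tested AML1-ETO associated genes, edgeR called none across all 5 libraries, with 7 higher and 3 lower at an unadjusted p under 0.05, and 2 were higher and 1 lower adjusted over the list alone. DESeq2 called 6 higher and 2 lower, Runx1t1 and Runx1 among the higher, and limma-voom 7 and 3. Without deleted 6, 9 were called higher, among them Hes1, and 4 lower, among them Lmo2, at -1.71 ± 0.14 (adjusted p = 0.00142), and Ncam1; adjusted over the list alone the counts were 10 and 4. The set did not pass camera (adjusted p = 0.468, and 0.251 without deleted 6), while with DESeq2 it was called higher (median 0.11, adjusted p = 0.0242).

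**Figure D2:**
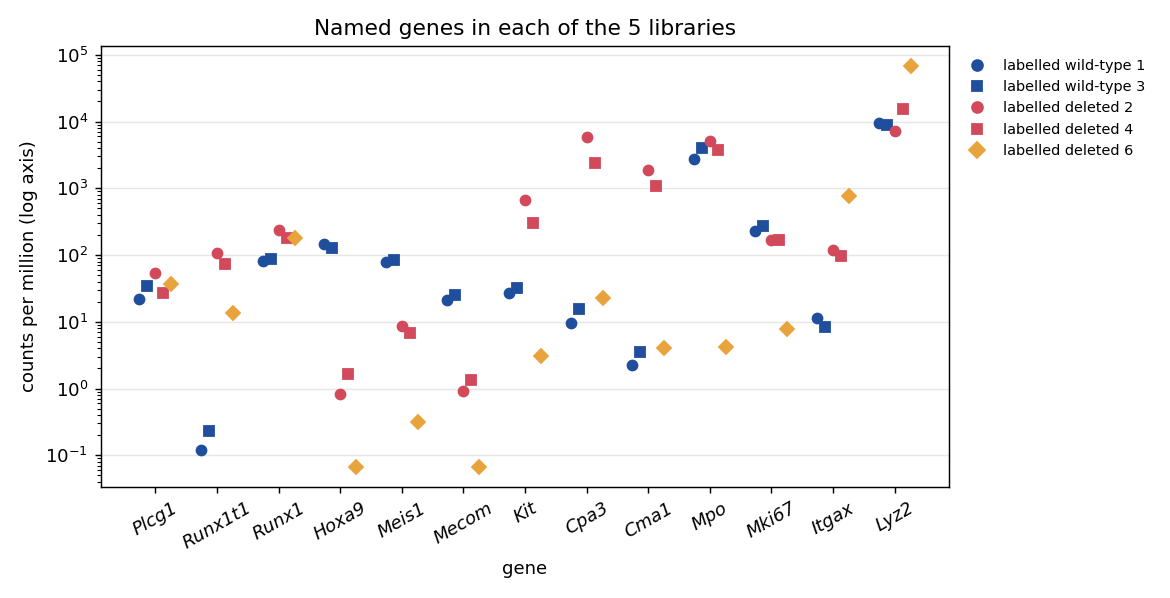
Points give CPM of 13 genes in each of the 5 libraries on a log axis; blue marks the libraries labelled wild-type, red deleted 2 and 4, and orange deleted 6. Hoxa9 lies at 128 CPM or more in both wild-type libraries and at 1.66 CPM or less in the deleted ones, Runx1t1 lies the other way, and Kit and Cpa3 are high in deleted 2 and 4 alone.

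Mast cell genes had the largest median log2 fold change of the 32 tested lists, with a list mean far above wild-type in deleted 2 and 4 and below it in deleted 6. Mitf, a transcription factor of mast cells and other lineages, was an exception, at 12.8 and 12.1 CPM in wild-type, 24.5 and 32.3 CPM in deleted 2 and 4, and 67.3 CPM in deleted 6. In 6 of the 17 members every deleted library lay above both wild-type libraries, where chance gives 10% for a single gene and all tested genes gave 22.4%. The members varied together (estimated correlation 0.759), so they do not count as independent. Cpa3, the carboxypeptidase of mast cell granules, was at 9.64 and 15.7 CPM in the wild-type libraries, 5961 and 2357 CPM in deleted 2 and 4, and 23.1 CPM in deleted 6. Without deleted 6, Tpsb2, a mast cell tryptase, rose by 9.76 ± 0.46 on the log2 scale and the IgE receptor chain Fcer1a by 9.34 ± 0.55 (SE; edgeR adjusted p = 0.000378 and 0.000765). All 17 tested mast cell and basophil genes were called higher in that fit. With all 5 libraries edgeR called none, either genome-wide or adjusted over the list alone, with 11 higher at an unadjusted p under 0.05, while DESeq2 called 12 higher and limma-voom 7. Of the 12 genes with the largest rise without deleted 6, Tph1, Tpsb2, Hs6st2, Car8, Fcer1a, Cma1, Rab27b, Runx1t1, Ctla2a, Mcpt4, Tpsab1 and Cpa3, the fixed mast cell list holds 6. The tryptases and chymases belong to families of similar genes, so counts can be split between members. Across all 5 libraries the list's median log2 fold change was 7.26 (camera adjusted p = 0.00295). The call was lost with an estimated correlation (adjusted p = 0.783), without deleted 2 (median 3.83, adjusted p = 0.113) and without deleted 4 (median 5.31, adjusted p = 0.05004).

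Platelet lineage genes were higher in deleted 2 and 4 as a list, while in deleted 6 its members went both ways. The list's mean log2 CPM lay 1.97 and 1.81 above the wild-type mean in deleted 2 and 4 and at -0.01 in deleted 6, where Itgb3 was at 161 CPM, against 10.1 and 15.7 CPM in wild-type, and Nfe2 at 2.89 CPM, against 299 and 324 CPM. In 4 of 13 members every deleted library lay above both wild-type libraries and in 1 below. For a single gene chance gives 10% each way, and all tested genes gave 22.4% and 23.7%. The megakaryocyte and platelet list (13 tested genes) had a median log2 fold change of 2.60 (camera adjusted p = 0.0273). With an estimated correlation its adjusted p was 0.783. The call was also lost without wild-type 1, deleted 2 or deleted 4 (adjusted p = 0.0893, 0.113 and 0.0807; medians 2.81, 2.16 and 3.02), and with no filter on low counts (0.0795; median 2.16). Without wild-type 3 or deleted 6 the median was 1.70. Itgb3 and Vwf, the von Willebrand factor, had the smallest p: Vwf was at 8.68 and 15.2 CPM in wild-type and 46.7, 63.3 and 156 CPM in deleted 2, 4 and 6. Adjusted over the list alone, 2 members were higher. At an unadjusted p under 0.05 in edgeR 5 were higher and 0 lower. DESeq2 and limma-voom each called 4 higher and 0 lower. Without deleted 6 edgeR called 6 of 12 members higher, led by Gp1ba at 5.26 ± 0.57 and Itga2b at 4.19 ± 0.65, and 1 lower, Nfe2 at -0.87 ± 0.20; adjusted over the list alone 8 were higher and 1 lower. Of 12 erythroid genes 4 were called higher without deleted 6, among them the transcription factor Gata1 (5.01 ± 0.48, adjusted p = 0.00210). Of 6 eosinophil genes 2 were called higher, Il5ra and Siglecf. There, 5 erythroid genes were higher and 2 lower adjusted over the list alone, and 2 eosinophil genes were higher and 1 lower. Across all 5 libraries neither list passed camera (adjusted p = 0.982 and 0.805), while with DESeq2 the erythroid list was called higher (median 1.70, adjusted p = 0.0222).

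Neutrophil granule genes were lower under the deleted label as a list, mostly through deleted 6. The list's mean log2 CPM lay at -0.68, -0.35 and -6.09 from the wild-type mean in deleted 2, 4 and 6, and at -0.20 and 0.20 in wild-type 1 and 3. Every deleted library lay below both wild-type libraries in 11 of 24 members and above in 1, where all tested genes gave 23.7% and 22.4%. Without deleted 6, 11 of 24 members had a positive log2 fold change. Elane, neutrophil elastase, was at 4869 and 4977 CPM in the wild-type libraries, 831 and 848 CPM in deleted 2 and 4, and 1.45 CPM in deleted 6. Across all 5 libraries, the list (24 genes) had a median log2 fold change of -0.69 (camera adjusted p = 0.0162). With an estimated correlation the adjusted p was 0.783. Leaving out single libraries, the median was -0.18 without deleted 6 (adjusted p = 0.0697), -1.13 without deleted 2 and -1.21 without deleted 4. The call was also lost with library totals alone (-0.78, adjusted p = 0.0708) and in limma-voom (-0.31, adjusted p = 0.325), and lane 4 alone gave a median of -0.33. edgeR called no member across all 5 libraries, genome-wide or adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05; DESeq2 called 2 lower, and limma-voom 1 higher and 2 lower. Without deleted 6 edgeR called 9 members lower, with Elane at -2.54 ± 0.17 (adjusted p = 0.000967), and 1 higher, the chitinase-like Chil3 at 2.13 ± 0.19; adjusted over the list alone 10 were lower and 3 higher. Mpo was not called (0.42 ± 0.26, adjusted p = 0.344). Of 19 monocyte and macrophage genes, 4 were called lower without deleted 6, among them Irf8 and Ly6c2 (-2.13 ± 0.32 and -2.08 ± 0.30), and 1 higher, Adgre1 (1.19 ± 0.27); adjusted over the list alone these were 5 and 2. That list did not stand apart (camera adjusted p = 0.369, and 0.0534 without deleted 6); its median across all 5 libraries was 0.09, while its mean of -0.27 and its camera direction were lower. The median was -0.05 without wild-type 1, 0.38 without deleted 2, 0.35 without wild-type 3, -0.09 without deleted 4 and -0.67 without deleted 6, so its sign is not settled.

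Several antigen presentation genes were higher in all 3 deleted libraries. In 10 of 17 listed genes every deleted library lay above both wild-type libraries, and in 2 every one lay below. For a single gene chance gives 10% each way, and all tested genes gave 22.4% and 23.7%. Members varied together (estimated correlation 0.374), so they do not count as independent. Itgax, the integrin CD11c of dendritic cells and macrophages, was at 11.5 and 8.25 CPM in wild-type, 120 and 97.5 CPM in deleted 2 and 4, and 756 CPM in deleted 6. H2-Aa, a class II histocompatibility chain, was at 6.99 and 11.2 CPM, then 60.9, 75.6 and 472 CPM. The dendritic cell and antigen presentation list (17 genes) had a median log2 fold change of 3.11 (camera adjusted p = 0.0244). Its adjusted p was 0.783 with an estimated correlation. It was 0.0950 without wild-type 1 (median 2.24), 0.0597 without deleted 6 (median 1.90) and 0.0663 in lane 4 alone (median 1.31), 0.0576 with lane as a term and 0.0738 with the stricter filter; in limma-voom the median was 1.88. edgeR called no member across all 5 libraries, with 7 higher and 1 lower at an unadjusted p under 0.05, and 5 were higher and 1 lower adjusted over the list alone. DESeq2 and limma-voom each called 6 higher and 1 lower. Without deleted 6, 6 of 16 members were called higher, with Itgax at 3.47 ± 0.22 (adjusted p = 0.000799), and 2 lower, Tcf4 at -1.30 ± 0.13 and H2-DMb1 at -0.64 ± 0.16; adjusted over the list alone these were 6 and 3. Markers of other cells gave no call as sets across all 5 libraries in edgeR's setting. For the B cell, T and NK cell, and stromal and endothelial lists the camera adjusted p was 0.131, 0.982 and 0.197. The B cell list had a median of -0.92 (-0.58 without wild-type 3) and was called lower without deleted 4 (median -2.98, adjusted p = 0.0160), and the stromal list, with a median of 3.12, was called higher with DESeq2 (median 2.49, adjusted p = 0.0242). Without deleted 6, the antibody heavy chain gene Ighm was called lower (-2.92 ± 0.35) and the interleukin-7 receptor Il7r higher (1.71 ± 0.17). The stem cell factor gene Kitl was called higher there too (1.74 ± 0.35), the only called member of the 9 stromal genes. Adjusted over the list alone, that fit gave 2 B cell genes higher and 4 lower, 3 T and NK cell genes higher and 1 lower, and 2 stromal genes higher.

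Cell cycle genes were lower in every deleted library. Of 40 S phase genes, 38 had each deleted library below both wild-type libraries, as did 45 of 49 G2 and M phase genes. For a single gene chance gives 10%, and all tested genes gave 23.7%. Members of each list varied together, with estimated correlations of 0.984 and 0.920, so they do not count as independent observations. The median log2 fold changes were -1.01 and -1.02 across all 5 libraries (camera adjusted p = 4.14e-05 and 4.46e-05). They were -0.50 and -0.46 without deleted 6 (2.04e-09 and 7.41e-09). With an estimated correlation the adjusted p was 0.783 for both lists across all 5 libraries and 0.693 for both without deleted 6. Lane 4 alone gave medians of -0.57 and -0.46, and limma-voom -0.64 and -0.57. Cdc45, a replication factor, was at 121 and 122 CPM in wild-type, 68.4 and 65.1 CPM in deleted 2 and 4, and 4.12 CPM in deleted 6. Rrm2, a ribonucleotide reductase chain, was at 616 and 689 CPM, then 404, 348 and 6.51 CPM. edgeR called no member of either list across all 5 libraries, genome-wide or adjusted over the list alone, with 1 S phase gene lower and no G2 and M phase gene at an unadjusted p under 0.05; DESeq2 and limma-voom called none. Without deleted 6 edgeR called 13 S phase genes lower, with Cdc45 at -0.85 ± 0.12, and 11 G2 and M phase genes lower, with Ccnb2 at -0.76 ± 0.13 and Smc4 at -0.68 ± 0.13. Adjusted over the list alone these were 30 and 28, and no member was higher, as with DESeq2 there (20 and 19 lower) and with edgeR at an unadjusted p under 0.05 (30 and 33 lower). Among 21 inhibitors of the cycle and quiescence genes, 4 were called higher without deleted 6, among them Cdkn2b and Cdkn1c, and 3 lower, among them Cdkn2c and Pdcd4 (camera adjusted p = 0.638, and 0.468 across all 5 libraries); adjusted over the list alone 4 were higher and 4 lower.

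Genes of ribosome synthesis had lower list medians under the deleted label, mostly through deleted 6. Every deleted library lay below both wild-type libraries in 16 of 36 biogenesis genes (above in 2) and 20 of 52 ribosomal protein genes (above in 0). All tested genes gave 23.7% below and 22.4% above. The ribosomal protein mean in deleted 2, at -0.14 from the wild-type mean, lay above that of wild-type 3, at -0.21. The MYC and ribosome biogenesis list (36 genes) had a median log2 fold change of -0.43 (camera adjusted p = 0.00295) and the cytosolic ribosomal proteins (52 genes) one of -0.54 (4.46e-05). With an estimated correlation both had an adjusted p of 0.783. Without deleted 6 the medians were -0.19 and -0.23 (adjusted p = 0.0383 and 0.00605), with an adjusted p of 0.792 for both with an estimated correlation. In lane 4 alone they were -0.09 and -0.03 (adjusted p = 0.383 and 0.804). Without wild-type 1 the biogenesis list had an adjusted p of 0.0567, and the ribosomal proteins a median of -0.35; limma-voom gave medians of -0.27 and -0.30. Myc was at 298 and 275 CPM in wild-type, 184 and 133 CPM in deleted 2 and 4, and 15.9 CPM in deleted 6; it was called lower without deleted 6 (-0.84 ± 0.18, edgeR adjusted p = 0.0306), as was Nop56 (-0.60 ± 0.14), and neither passed adjusted over the list alone. edgeR and DESeq2 called no ribosomal protein gene in either fit, and limma-voom none across all 5 libraries, with 0 at an unadjusted p under 0.05 in edgeR; ribosomal protein counts are uncertain because of their many pseudogenes.

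**Figure D3:**
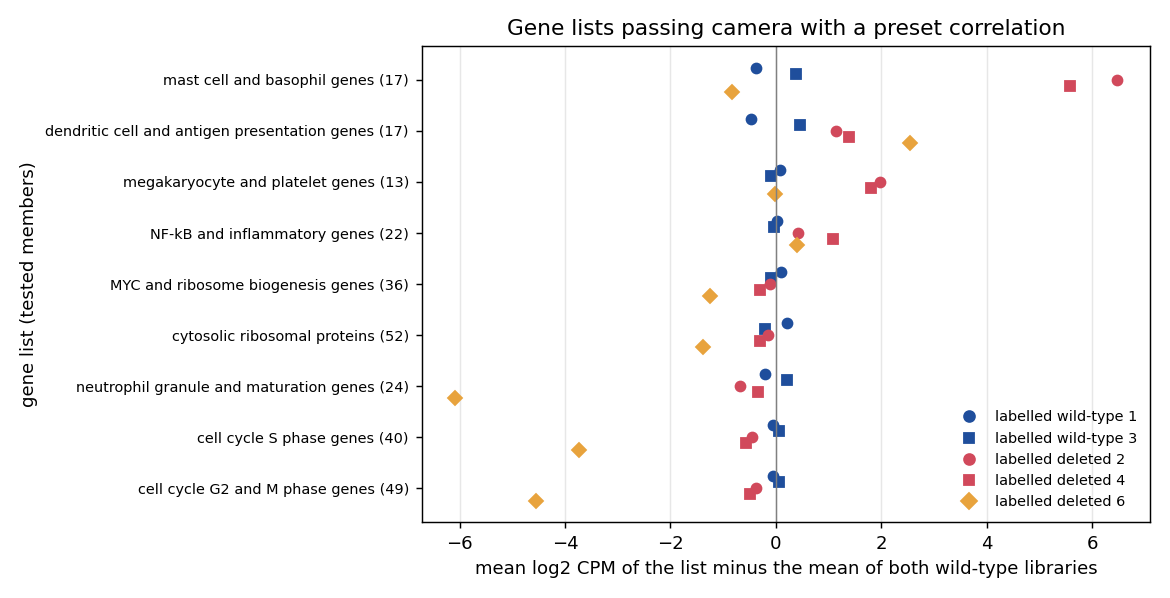
For each of the 9 gene lists with a camera adjusted p below 0.05, points give a library's mean log2 CPM over the list minus the mean of both wild-type libraries; blue marks wild-type, red deleted 2 and 4, and orange deleted 6. The mast cell list lies 6.48 and 5.58 higher in deleted 2 and 4 and at -0.83 in deleted 6, and both cell cycle lists lie below the wild-type libraries in all 3 deleted libraries.

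Genes of phospholipase C signalling did not move together. Of 10 tested phospholipase C genes edgeR called none across all 5 libraries, with 1 higher and 1 lower at an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. DESeq2 and limma-voom each called 1 higher and 1 lower. Without deleted 6 Plcl1 and Plcb4 were called higher (3.31 ± 0.79 and 1.52 ± 0.35) and Plcb1 lower (-3.00 ± 0.33, edgeR adjusted p = 0.00303). Its camera adjusted p was 0.982, with a direction opposite in sign to the median of 0.10 and the mean of 0.24. The median was 0.02 without wild-type 1, -0.04 without deleted 2, 0.30 without wild-type 3 and 0.20 without deleted 4. Without deleted 6 the direction was again opposite to the median of 0.02 and mean of 0.18. Among 35 calcium, calmodulin and NFAT genes, 5 were called higher without deleted 6, including the inositol trisphosphate receptor Itpr2 (1.59 ± 0.20, adjusted p = 0.00464), and 1 lower, the calcium pump Atp2b4 (-1.76 ± 0.33). Among 36 diacylglycerol, PKC and RAS-MAPK genes, 5 were called higher, with Prkcq at 6.61 ± 0.75 and Dusp4 at 4.38 ± 0.18, and 3 lower, among them Spry1 (-2.14 ± 0.43). Across all 5 libraries neither set passed camera (adjusted p = 0.567 and 0.314), while with DESeq2 the RAS-MAPK list was called higher (median 0.24, adjusted p = 0.0187). Across all 5 libraries edgeR called 0 members of both lists genome-wide, with 5 higher and 1 lower in each at an unadjusted p under 0.05. DESeq2 called 4 calcium genes higher and limma-voom 5 higher and 2 lower, and of the RAS-MAPK genes DESeq2 called 4 higher and 1 lower and limma-voom 5 and 3. Within edgeR, adjusted over the list alone, 1 calcium gene was higher, and of the RAS-MAPK genes 1 was higher and 1 lower. Without deleted 6, adjusted over the list alone, 5 calcium genes were higher and 2 lower, and 10 RAS-MAPK genes were higher and 6 lower.

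Inflammatory genes had a higher list mean in each deleted library than in wild-type. Across all 5 libraries edgeR called 0 members, as it called 0 of all 16120 tested genes. Every deleted library lay above both wild-type libraries in 9 of 22 members and below in 2, where all tested genes gave 22.4% and 23.7%. The NF-kB and inflammatory list (22 genes) had a median log2 fold change of 0.67 (camera adjusted p = 0.0244). With an estimated correlation its adjusted p was 0.783, and it was 0.0567 without wild-type 1 (median 0.68), 0.163 without deleted 4 (0.65), 0.0521 in lane 4 alone (0.56) and 0.0555 with lane as a term (0.55). Of its members, 2 were higher adjusted over the list alone. DESeq2 called 3 members higher across all 5 libraries and limma-voom 4, and neither called any lower. Without deleted 6 edgeR called Il6, Traf1 and Tnfaip3 higher, with Traf1 at 2.05 ± 0.24 (adjusted p = 0.00413), and none lower. There 10 members were higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 5 higher and 0 lower. Among 25 immediate early and dissociation stress genes 8 were called higher without deleted 6 and none lower. Among the higher were the heat shock gene Hspa1a at 3.02 ± 0.54 and Atf3 at 1.62 ± 0.26. In that fit 13 were higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 11 higher and 1 lower. Across all 5 libraries DESeq2 called 5 of these genes higher and limma-voom 8, with 0 lower. That list had a camera adjusted p of 0.197, and 0.0506 without deleted 6. It was called higher with DESeq2, limma-voom and no filter (adjusted p = 0.00461, 0.0227 and 0.0286). Adjusted over the list alone, 13 immediate early genes were higher and 1 lower there, and of the p53 target genes 6 were higher and 1 lower. Hspa1a shares reads with its near-identical copy Hspa1b. The 25 p53 target genes gave 5 called higher without deleted 6, with Plk2 at 2.58 ± 0.30 (camera adjusted p = 0.0596, and 0.0776 without deleted 6), and the p53 list was called higher with DESeq2, with no filter and without deleted 4 (adjusted p = 0.00466, 0.0168 and 0.0399). Of 30 interferon response genes 3 were called lower without deleted 6, with Gbp3 at -2.72 ± 0.18 and Psmb9 at -1.07 ± 0.17. The interferon list's camera adjusted p was 0.696 across all 5 libraries, with a direction opposite to its median of 0.07 and mean of 0.20. The median was -0.12 without wild-type 1, 0.38 without wild-type 3 and -0.23 without deleted 6. Without deleted 2 it was called higher (median 0.41, adjusted p = 0.0368), and in lane 4 alone lower (median -0.50, adjusted p = 0.0456); with library totals alone its median was -0.21.

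Metabolic, stress and homing lists were not called as sets across all 5 libraries. Without deleted 6, edgeR called 4 of 25 unfolded protein and amino acid stress genes higher and 3 lower, and 4 of 24 homing and adhesion receptors higher and 5 lower. Of 24 glycolysis and hypoxia genes 1 was called higher and 3 lower, of 22 apoptosis regulators 2 higher, and of the oxidative phosphorylation and mitochondrially encoded genes 0, with 0 at an unadjusted p under 0.05 and 0 with DESeq2. The camera adjusted p was 0.805 for 49 nuclear genes of oxidative phosphorylation, 0.570 for 8 mitochondrially encoded genes, 0.173 for 24 glycolysis and hypoxia genes and 0.129 for 22 cholesterol synthesis genes. It was 0.468 for 22 apoptosis regulators, 0.740 for 25 unfolded protein and amino acid stress genes, 0.982 for 24 homing and adhesion receptors and 0.0746 for 16 replication-dependent histone genes. Without wild-type 3 the oxidative phosphorylation list was called lower (median -0.13, adjusted p = 0.0425). The cholesterol list was called lower with limma-voom, lane as a term, lane 4 alone and library totals alone (adjusted p = 0.000426, 0.00231, 0.00295 and 0.0355; medians -0.37, -0.37, -0.36 and -0.37). It was also called lower without deleted 6 (median -0.33, adjusted p = 0.00522), with Fdps and Pmvk at -0.65 ± 0.15 and -0.62 ± 0.15; with an estimated correlation its adjusted p was 0.792. The histone list was called lower without deleted 2, 4 or 6 (medians -1.47, -1.35 and -0.65, adjusted p = 0.0368, 0.0483 and 0.0383). Poly(A) priming would miss histone transcripts without a tail, so these counts need not follow histone expression. The list also had low values, at a mean log2 CPM of 1.29 and 1.39 in wild-type and 1.00, 0.83 and -0.91 in deleted 2, 4 and 6. With an estimated correlation its adjusted p without deleted 6 was 0.693, and the 2 members edgeR called there, Hist1h2bc and Hist1h1c, were higher. Single genes called without deleted 6 included the amino acid exchanger Slc7a11 (2.63 ± 0.28) and the stress factor Ddit3 (1.89 ± 0.21), both higher. They also included the survival gene Bcl2l1 (0.89 ± 0.16, higher), the hypoxia sensor Egln3 (-1.68 ± 0.25, lower) and the chemokine receptor Ccr2 (-1.82 ± 0.40, lower). Adjusted over the list alone, the fit without deleted 6 gave 8 homing genes higher and 8 lower, 4 stress genes higher and 4 lower, 1 glycolysis gene higher and 5 lower, and 3 histone genes higher and 6 lower. The apoptosis list's median without deleted 6 was -0.01, opposite in sign to its mean of 0.23 and its camera direction.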

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

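The fit with bias-adjusted deviances in edgeR was chosen after the data were seen, as were the counts of list members without deleted 6; the other alternatives were fixed before. No paired analysis was possible because the labels name no pairs between the 2 groups. Deleted 6 is a limit of these fits. edgeR called 0 genes either way across all 5 libraries, with 2396 at an unadjusted p under 0.05, and 0 again with DESeq2's size factors, upper-quartile factors, library totals alone, a stricter filter, robust fitting, a 1.5-fold minimum or bias-adjusted deviances. Calls higher and lower were 838 and 396 with DESeq2, 1230 and 947 with limma-voom, 163 and 115 with no filter, 197 and 132 with lane as a term, and 211 and 131 in lane 4 alone. Lanes 3 and 5 hold 1 library each, so the lane term removes the same pair of libraries as lane 4 alone does. Leaving out single libraries gave 0 to 1245 higher and 0 to 800 lower; the calls came only without deleted 6 (DESeq2 there: 1677 and 1111). The fits without wild-type 1 or 3 and in lane 4 alone assume that the lone wild-type library varies like the deleted ones. Of the edgeR calls without deleted 6, 1047 were also DESeq2 calls across all 5 libraries, all in the same direction. Both fits use every library other than deleted 6, so this agreement in direction was nearly fixed in advance. Library totals alone moved the median log2 fold change of all genes to -0.19.

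Plcg1 stayed positive and uncalled in every alternative (log2 fold change 0.16 to 0.82, and 0.19 to 0.82 when single libraries were left out). All 20 genes with the smallest p kept their direction in every alternative and passed with DESeq2, limma-voom, no filter, both lane settings and without deleted 6. These settings reuse the counts that picked the genes, so this is no independent support. Camera called 4 lists higher and 5 lower; higher lists numbered 10 with DESeq2, 2 with lane as a term, 2 in lane 4 alone and 1 to 4 when single libraries were left out, where lower lists numbered 4 to 7. Both counts were 0 with an estimated correlation and 0 with fry. Both cell cycle lists kept their camera call in every setting but the estimated correlation. The interferon list reversed without deleted 2 (median 0.41, adjusted p = 0.0368, against 0.696; 0.0368 to 0.957 over its alternatives, with medians from -0.23 to 0.41 when single libraries were left out); the cause was not tested. Robust fitting, the 1.5-fold minimum and bias-adjusted deviances leave camera's input as it is and gave no list values. Over all genes with a count, Spearman correlations were 0.906 between the wild-type libraries, 0.910 between deleted 2 and 4, 0.893, 0.897, 0.895 and 0.898 between these groups, and 0.875, 0.886, 0.877 and 0.891 with deleted 6; low counts lower them.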

Other observations

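Further genes differed widely between libraries, and these were chosen after their values were seen. Abcc8, a subunit of a potassium channel, was at 11.9 and 15.9 CPM in the wild-type libraries and at 0.0175, 0 and 0.407 CPM in deleted 2, 4 and 6. Nrg1, an ERBB receptor ligand, was at 13.6 and 10.7 CPM, then 0.280, 0.0566 and 0.0226 CPM. Vegfc, a lymphatic growth factor, went the other way, at 0.145 and 0 CPM in wild-type and 19.7, 9.59 and 13.5 CPM in deleted libraries. Mecom, a stem cell transcription factor, was at 21.4 and 24.8 CPM in wild-type and 0.929, 1.36 and 0.0678 CPM in deleted libraries. The macrophage elastase Mmp12 was at 756 and 445 CPM in wild-type, 5822 and 7249 CPM in deleted 2 and 4, and 26802 CPM in deleted 6. Col1a1, a collagen of fibroblasts, was at 23.9 CPM in deleted 2 and at 1.21 CPM or less in the other 4 libraries.

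Of the tests below, the one on Kmt2a was written down before its value was seen, and the others were chosen after. Hoxa genes and Meis1 were high, and Runx1t1 near 0, in both libraries labelled wild-type. A difference in depth or scaling is argued against: scaled by library totals alone, the lowest deleted library exceeded the highest wild-type library 41.6-fold in Runx1t1, while library totals differed at most 1.53-fold. Hoxa9 went the opposite way, with 6000 and 7099 counts in wild-type and 48, 88 and 3 in deleted 2, 4 and 6. A single factor per library cannot move both genes in opposite directions. A hypothesis is that the wild-type libraries hold another leukaemia, such as one driven by a human KMT2A fusion, whose reads may align to mouse Kmt2a. Kmt2a was then predicted lower in deleted libraries in the fit without deleted 6. Its log2 fold change there was -0.89 ± 0.14 (SE, edgeR adjusted p = 0.0108). Across all 5 libraries it was -0.81 ± 0.18 and not called (edgeR adjusted p = 0.200). Kmt2b, Kmt2c and Kmt2d, which were not part of the prediction, had -0.20, 0.34 and -0.09 without deleted 6. The genotype itself stays open: Plcg1 had a log2 fold change of 0.48 ± 0.37, and the label goes with every other difference between these groups. The design thus cannot tell the genotype and a difference in the leukaemia apart. With 5 and 13 Runx1t1 counts, the wild-type libraries showed almost none of the labelled fusion, if its reads align to the mouse gene. Deleted 2, 4 and 6 had 6035, 3921 and 598.

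Mast cell and basophil genes were high in deleted 2 and 4, together with Kit. A candidate explanation is that cells of the mast lineage, which carry Kit and would pass a Kit gate, are part of these libraries, which was left undecided: 14 of the 17 listed genes were more than 4-fold higher in both than in both wild-type libraries, but all 17 had already been called higher, so this count only describes the pattern. Cpa3 was at 5961 and 2357 CPM and Cma1 at 1871 and 1075 CPM, none of the 17 is in another list, and 7 were above 5 CPM in both wild-type libraries. Mast cell genes switched on within the leukaemia cells would give the same bulk values, so these cannot be told apart. Whether the genotype raises these genes stays open, since in deleted 6 only 1 of the 17 was more than 4-fold higher than in wild-type, and a single library that differs in many ways excludes nothing.

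Deleted 6 was low in progenitor, granule and cell cycle genes. A shallow library is argued against, as its total of 57.1 M gene counts was more than the 53.4 M of the next library. Dilution of cells like those of deleted 2 and 4 by another cell type, such as macrophages, would lower transcripts that the other cells lack by a common factor. It is argued against as the whole cause if the other cells lack Runx1t1. Runx1t1 was 6.65-fold lower than the mean of deleted 2 and 4, and Mpo, Elane, Prtn3 and Ctsg were 279-fold to 1054-fold lower, at least 42.0 times as much. The Y-linked Ddx3y was 317-fold lower, and Kdm5d and Eif2s3y had 0 counts in deleted 6. Male cells, such as those of deleted 2 and 4, could thus be only a small part of deleted 6. Female cells of the same type would lack Y-linked transcripts too, so these genes do not limit their share. The granule genes limit only cells that express them at the levels of deleted 2 and 4. Deleted 6 may come from a female source, unlike the rest: it had 5375 counts of Xist, the X-inactivation transcript, against at most 3 in any other library, and the Y-linked Ddx3y was at 0.271 CPM against 64.0 to 92.4 CPM. A Kit gate would remove macrophages, yet Kit was at 3.08 CPM in deleted 6, against 26.8 to 672 CPM in the other libraries, so what the gate kept is unknown; mature leukaemia cells and a mixture of other cells both stay open, and no biological explanation from the design was tested for this library.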
